A study of Mus musculus with 8 samples.

How the data were processed

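MicroRNAs were measured in 8 samples of mouse kidney with Agilent mouse miRNA arrays, on which total RNA labelled with Cy3 is hybridised to short probes complementary to mature miRNAs. Per the labels, 4 arrays came from mice given lipopolysaccharide (LPS, a component of the bacterial outer membrane) into the peritoneal cavity at 10 µg per g of body weight, and 4 from sham mice given saline. Kidneys were taken after 24 h, 30 mg of tissue was extracted and 100 ng of total RNA was labelled. The labels number the samples within each group but do not state that each came from its own animal, so p-values measure the spread between these samples.

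The spot intensities were deposited by the authors as the scanner software's output for each array, and per the file headers they had been background-subtracted with a spatial detrending step and not scaled between arrays. The submitters' processing notes name Agilent Feature Extraction 12.0.3.1. A second table deposited by the authors gives 1 linear ratio per miRNA and array. Set against the scanner values of 383 miRNAs with a positive signal throughout, 100% of its values lay within 0.01 log2 of the manufacturer's total signal per miRNA after 1 factor per array and 1 per miRNA, so its scale is linear and each miRNA is centred. The origin of the array factors is not given in the sources used here. The medians of its columns were 0.995, 1.06, 1.05 and 0.980 for sham replicates 5, 6, 7 and 8, and 0.958, 0.960, 1.01 and 1.03 for LPS replicates 6, 10, 11 and 12. It was used only as an alternative.

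All 8 arrays lay on 1 slide and were read in 1 scan. The sham arrays filled row 1 and the LPS arrays row 2 of the slide, so slide row and group cannot be told apart. Each of the 4 columns held 1 array of each group, and column was tried as a block. Each array had 58594 spots, of which 56430 were not controls, for 4415 probes and 1881 miRNAs, with 7 to 30 spots per probe and 1 to 4 probes per miRNA. No non-control spot was saturated.

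Spots flagged as outliers were left out and the remaining spots of a probe averaged. Each array was divided by its 75th percentile over the 551 probes above background on all 8 arrays, and the probes of a miRNA were summed. A miRNA counted as detected on an array when more than 50% of the spots of any of its probes were flagged well above background. Sums were floored at the median over arrays of the smallest detected value (-4.68 on the log2 scale) and log2-transformed. Values are therefore log2 signals relative to the 75th percentile of the array. The 338 miRNAs detected on every array of at least 1 group were tested, and 0.851% of their values were at the floor. Values at the floor hide spread between samples, so p-values of the miRNAs concerned measure it only in part. The number of arrays limits the precision.

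LPS and sham arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided, no covariates), with Benjamini-Hochberg adjustment over the 338 miRNAs and a threshold of 0.05. Where every array of a group was below background, only a bound is given, for the miRNA's brightest probe, against the higher of the lowest signal among probes above background on each array and the probe's own. Bounds on the sum of probes, computed first, were larger and are not given. Of 21 lists of miRNAs fixed beforehand, the 14 with at least 3 tested members were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. Single values per array were compared by exact permutation, for which 4 against 4 arrays allow no p below 0.0286. On 50 simulated data sets of 338 miRNAs with the spread of this comparison and 60 miRNAs changed, the fit recovered 57.4% of changes of 1.25-fold, 84.0% of 1.5-fold and 95.0% of 2-fold, with 4.57% of calls false. These data sets drew each miRNA independently and without a floor. The rates therefore do not cover miRNAs that vary together or lie at the floor. In 50 simulations of this comparison with no effect, keeping the correlation between the 338 miRNAs, camera with the preset correlation called at least 1 list in 24 and with the estimated correlation in 0.

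The miRNAs named were the 12 largest rises and the 12 largest falls among calls whose groups did not overlap, 7 chosen in advance (miR-21a-5p, miR-155-5p, miR-146a-5p, miR-223-3p, miR-122-5p, miR-210-3p and miR-192-5p), up to 4 members with the smallest p in each list, and those detected on all arrays of a group and none of the other. Other members, and other arms of a listed family, are named where a list count is broken down. These rules, the tests and the alternatives, unless said otherwise, were set before the data were examined. Alternatives covered scaling, background correction, the summary over probes, the filter, the floor, the variance model, slide column, the deposited ratio table and leaving out each array. Background correction with normexp added an offset of 50 to the signal, which in itself makes log2 differences of dim miRNAs smaller. Probe positions are those in the files, on mm9. Gene symbols came from a RefSeq table on GRCm38.p6, used for names, containing genes and, in a later check, distances between genes, and 331 of the 338 tested miRNAs matched. Of 268 tested miRNAs with at least 2 probes above background, 30 had probes of opposite sign, and of the 108 changed miRNAs with as many probes 0 did; the other changed miRNAs could not be checked this way.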

Results

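MicroRNA levels were compared between kidneys of mice 24 h after LPS, a model of septic acute kidney injury, and kidneys of saline-treated sham mice, with 4 arrays per group. Between 15.8% and 17.5% of non-control spots on each array were well above background. The arrays detected 351 ± 17.8 miRNAs in sham and 353 ± 7.80 in LPS kidneys (mean ± SD, n = 4 per group, 2-sided exact permutation p = 0.83). The log2 75th-percentile signal used for scaling was 8.94 ± 0.05 in sham and 9.01 ± 0.05 in LPS (n = 4 per group, 2-sided exact permutation p = 0.114). Log2 profiles correlated across miRNAs at 0.989 or more between arrays of a group and at 0.959 or more between groups, where miRNAs are not independent replicates.

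LPS kidneys differed from sham kidneys most in miR-21a, a miRNA known to rise in injured kidney. Its 5p arm was 4.65-fold higher (log2 difference 2.22 ± 0.08 SE, adjusted p = 1.95e-07), from 4.52 ± 0.10 to 6.73 ± 0.11 log2 units (SD, n = 4 per group). The 3p arm was not well above background on any sham array and its brightest probe was at least 17.6-fold higher after LPS (adjusted p = 4.16e-11 for the miRNA). This bound holds for the background subtraction used, and the log2 difference of the miRNA was 1.70 with normexp and 8.79 in the deposited ratio table. Sham values of miR-21a-3p lay at or near the floor (SD 0.06), so its p does not measure the spread between sham samples. MiR-155-5p, induced in activated macrophages, was 3.21-fold higher, and miR-132-3p higher by 1.39 log2 units, not an exact value because 2 of 4 sham arrays detected it. In total 136 of the 338 tested miRNAs changed, 50 higher and 86 lower in LPS kidneys, and 23 of them changed at least 2-fold, 19 higher and 4 lower. The groups did not overlap for 125 miRNAs, where chance gives 2.86% of those tested.

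**Figure D1:**
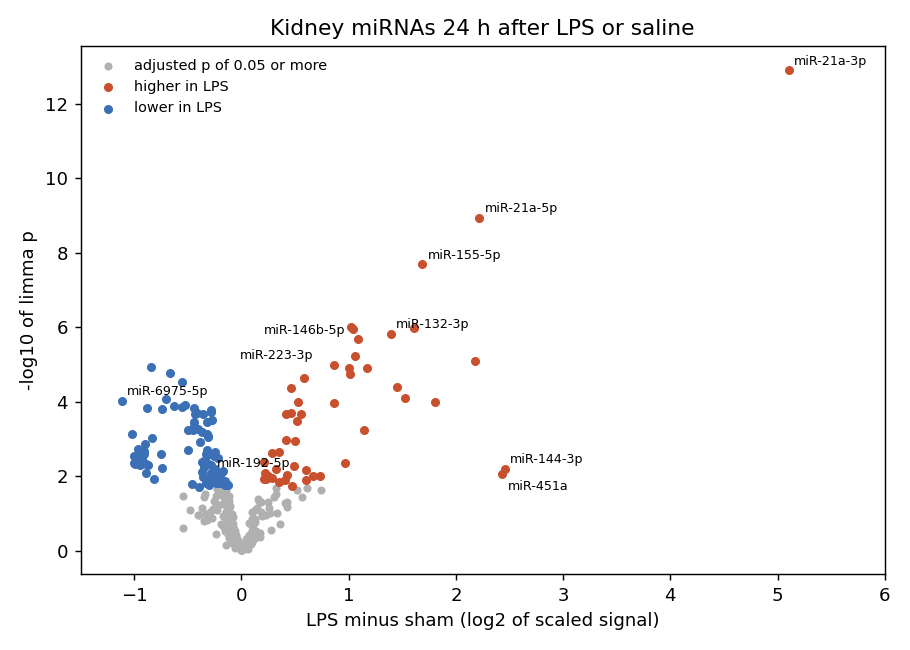
Each point is 1 of the 338 tested miRNAs, with the LPS minus sham difference (log2 of scaled signal) on the x axis and -log10 of the limma p on the y axis, and coloured points have an adjusted p under 0.05. The 50 higher miRNAs reach further from 0 than the 86 lower ones, and miR-21a-3p lies farthest right, at a fitted difference of 5.10 that is not exact because sham arrays were below background.

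The split between higher and lower calls depended on scaling. With the percentile taken over all probes 55 were higher and 53 lower, without scaling 57 and 49, and with cyclic loess 65 and 66. Scaling to labelling spike-ins, added after seeing the data, gave 34 and 151 and a median difference of all miRNAs of -0.23 in place of -0.08. Lower calls numbered 55 without sham replicate 7 and 56 without LPS replicate 11, and 80 miRNAs changed, 45 of them lower, with slide column as a block. With normexp background correction, the differences of 33 of the 55 named miRNAs that changed were over 1.5 times smaller, among them those of miR-155-5p (0.99), miR-132-3p (0.37), miR-146b-5p (0.20) and miR-18a-5p (0.34), which still passed the test. The offset of 50 makes differences of dim miRNAs smaller in itself, so the normexp values do not separate background from offset.

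Of 8 tested inflammation-induced miRNAs, 5 rose and 1 fell, counts that were the same when adjusted over the list alone. The risers were both arms of miR-21a, miR-155-5p, miR-132-3p and miR-146b-5p, a negative regulator of NF-κB signalling, which was higher by 1.09 ± 0.09 log2 units (SE, adjusted p = 8.79e-05), not an exact value because it was below background on 2 of 4 sham arrays (0.20 with normexp and 0.57 with the mean of logs over probes). MiR-212-3p, which shares a cluster with miR-132, fell by 0.45 ± 0.07 (adjusted p = 0.00166). MiR-146a-5p differed by 0.18 ± 0.09 (adjusted p = 0.166) and miR-9-5p by 0.33 ± 0.18 (adjusted p = 0.173). The miR-146a-5p level was -0.28 on sham replicate 5, -0.63 to -0.55 on the other sham arrays and -0.41 to -0.18 on LPS arrays. MiR-146a-5p gained the call in 2 of 30 alternatives. The list was shifted upward with camera (adjusted p = 2.07e-05), with adjusted p = 0.129 with an estimated correlation. On mm9, the probes of miR-21a-5p lie on chromosome 11 from 86397588 to 86397607, and those of miR-21a-3p from 86397631 to 86397645, inside the gene Vmp1, and both arms also have a second match. The miR-155-5p probes lie on chromosome 16 from 84714394 to 84714410, inside Mir155hg.

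**Figure D2:**
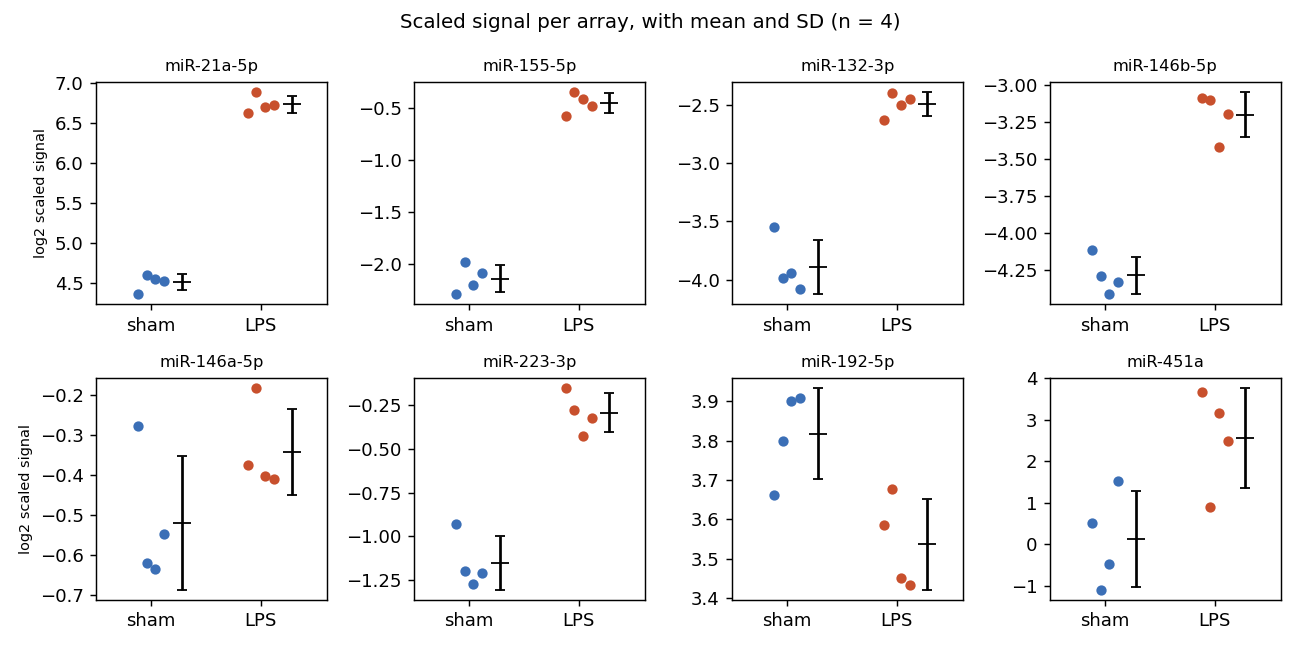
Log2 signal relative to the array's 75th percentile for 8 miRNAs, with 1 point per array, and mean and SD beside each group of 4; each panel has its own y axis. The 4 LPS arrays lie above the 4 sham arrays for miR-21a-5p, miR-155-5p, miR-132-3p, miR-146b-5p and miR-223-3p, and the groups overlap for miR-146a-5p, miR-192-5p and miR-451a.

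Among 11 tested members of the cluster of miR-17, miR-18a, miR-20a and miR-92a and its paralogs, which promote proliferation, 8 rose and 0 fell, also when adjusted over the list alone. MiR-18a-5p was 2.05-fold higher (1.04 ± 0.08, adjusted p = 6.11e-05), miR-20a-5p rose by 0.59 ± 0.07 and miR-92a-3p by 0.53 ± 0.08. The members of the paralogous cluster of miR-106b, miR-93 and miR-25 did not pass the test, with differences of 0.02 for miR-106b-5p, -0.12 for miR-93-5p and -0.001 for miR-25-3p. The list gave adjusted p = 5.87e-05 with camera and adjusted p = 0.496 with an estimated correlation. Of 5 miR-29 family members, 3 rose, led by miR-29a-5p (0.41 ± 0.13, detected on 3 of 4 sham arrays), miR-29a-3p (0.25 ± 0.07) and miR-29b-3p (0.23 ± 0.07), although the miR-29a-5p difference was -0.0004 with normexp background correction. With scaling to labelling spike-ins, miR-29a-3p and miR-29b-3p differed by 0.10 and 0.08 and were not called (adjusted p = 0.264 and 0.396). The passenger strand miR-29b-1-5p was below background in sham and its brightest probe at least 2.06-fold higher after LPS, but it was not called with normexp (0.12 log2, adjusted p = 0.0668). MiR-34b-5p (0.32 ± 0.09) and miR-34c-5p (0.35 ± 0.11) passed the test, while miR-34a-5p differed by 0.05 ± 0.22. With normexp, miR-34b-5p and miR-34c-5p differed by 0.10 and 0.05 and were not called (adjusted p = 0.106 and 0.343). In the list of miRNAs linked to acute kidney injury in the literature, 4 of 11 rose (miR-21a-5p, miR-155-5p, miR-132-3p and miR-18a-5p) and miR-494-3p fell by 0.46 ± 0.15 (adjusted p = 0.0429), or by 0.29 without LPS replicate 10. That list gave adjusted p = 0.00180 with camera and adjusted p = 0.496 with an estimated correlation. Calls were lost in 7 of 30 alternatives for miR-29a-3p and miR-29b-3p, 8 for miR-34b-5p, 12 for miR-34c-5p and 13 for miR-494-3p, including slide column as a block (adjusted p = 0.0636, 0.0619, 0.0535, 0.0958 and 0.0837), and in 11 of 29 for miR-29a-5p besides normexp, where it was not called either (adjusted p = 0.994). They were lost without sham replicate 7 or 8 for all 6 (adjusted p = 0.0516 to 0.0985), without LPS replicate 12 for all but miR-494-3p (0.0717 to 0.121). They were also lost without sham replicate 6 for miR-29b-3p, miR-34c-5p and miR-494-3p, LPS replicate 10 for miR-29a-5p and miR-34c-5p, LPS replicate 11 for miR-34c-5p and miR-494-3p, LPS replicate 6 for miR-29a-5p and miR-494-3p, and sham replicate 5 for miR-494-3p.

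Of 9 tested miRNAs abundant in kidney tubules, 6 fell, also when adjusted over the list alone. MiR-192-3p fell by 0.40 ± 0.07 (-0.16 with normexp, -0.23 with the mean of logs over probes and -0.27 with quantile normalization), miR-194-5p by 0.33 ± 0.07 and miR-192-5p by 0.28 ± 0.08 (adjusted p = 0.0277), and miR-204-5p by 0.19 ± 0.06, while miR-10a-5p (0.10) and miR-10b-5p (0.11) did not pass the test. The miR-192-5p call was lost without scaling (adjusted p = 0.173), with slide column as a block (0.0770), and without any of sham replicate 7, sham replicate 8, LPS replicate 11 or LPS replicate 12. That of miR-194-5p was lost without scaling (0.0688), and that of miR-196b-5p in 10 of 30 alternatives, including slide column as a block (0.0575) and leaving out any array except sham replicate 5 or LPS replicate 10 (0.0533 to 0.0811). Of 8 listed members of the miR-30 family 3 fell, miR-30e-3p by 0.36 ± 0.06, miR-30e-5p by 0.29 ± 0.07 and miR-30c-5p by 0.26 ± 0.06, the last 2 not called without scaling (adjusted p = 0.0921 and 0.0992). Outside the list, miR-30b-3p rose by 0.29 ± 0.07 (adjusted p = 0.0123) and miR-30c-1-3p fell by 0.88 ± 0.13. Camera did not call the tubule list (adjusted p = 0.187) or the miR-30 family (adjusted p = 0.129) as shifted against other miRNAs. Fry called both (adjusted p = 0.00706 and 0.0276).

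**Figure D3:**
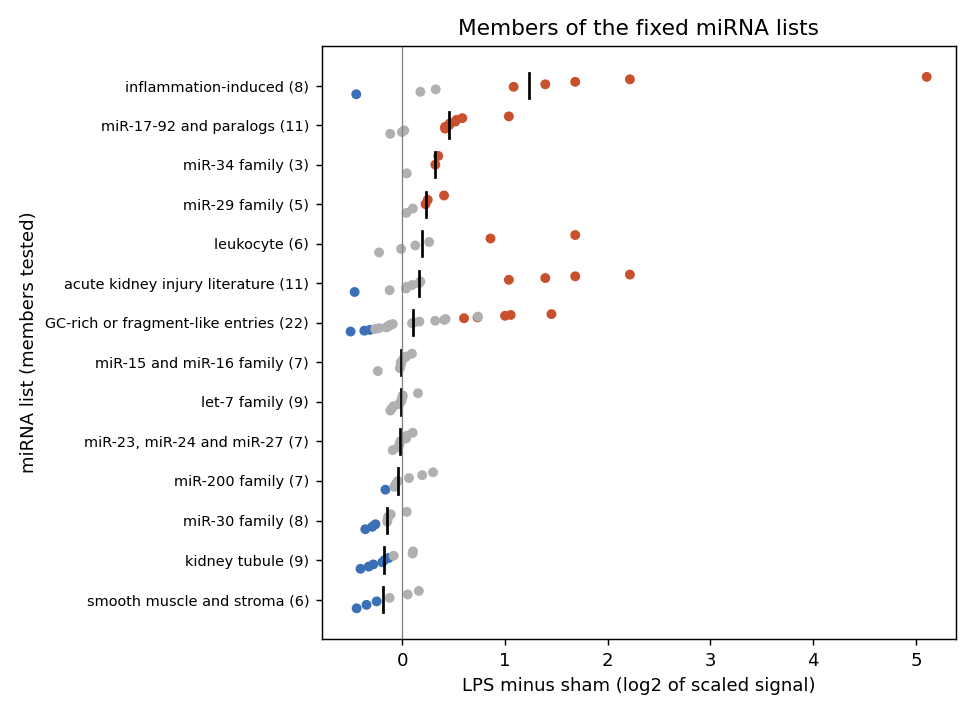
Each point is a tested member of a fixed list, with its LPS minus sham difference (log2 of scaled signal) on the x axis, red if higher and blue if lower at an adjusted p under 0.05, and a bar at the list median. Among the 14 lists with at least 3 tested members, the inflammation-induced list has the highest median, 1.24, and the smooth muscle and stroma list the lowest, -0.18.

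In several families few or no members passed the test: 0 of 9 let-7 members, 0 of 7 members of the miR-15 and miR-16 family and 0 of 7 of miR-23, miR-24 and miR-27 did, and 1 of 7 miR-200 family members fell (miR-429-3p, by 0.16 ± 0.05), with 0 called when adjusted over the list alone and the call lost in 13 of 30 alternatives, including leaving out any array except LPS replicate 10 (adjusted p = 0.0774 to 0.136). The let-7, miR-15/16, miR-23/24/27 and miR-200 medians were slightly negative while the sign of camera was positive, and camera called none of them (adjusted p = 0.967 for let-7 and 0.713 for the others). Hypoxia-induced miR-210-3p differed by 0.09 ± 0.22 (adjusted p = 0.777).

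MiRNAs of other cell types moved in different directions. The myeloid miR-223-3p was 1.81-fold higher (0.86 ± 0.09, adjusted p = 3.03e-04), and with miR-155-5p it made 2 of 6 leukocyte members that rose, while the pan-leukocyte miR-142a-3p differed by 0.26 ± 0.14 (adjusted p = 0.171) and the lymphocyte miR-150-5p by -0.22 ± 0.11 (adjusted p = 0.126). The miR-142a-3p level was 0.64 on sham replicate 5, -0.01 to 0.16 on the other sham arrays and 0.33 to 0.58 on LPS arrays. MiR-142a-3p gained the call in 2 of 30 alternatives. In smooth muscle and stroma, 3 of 6 fell, miR-145a-5p by 0.44 ± 0.08, miR-199b-5p by 0.35 ± 0.09 and miR-199a-5p by 0.25 ± 0.07. The miR-199a-5p call was lost in 12 of 30 alternatives, including slide column as a block (adjusted p = 0.0529), no scaling (0.175) and leaving out any array except sham replicate 8 or LPS replicate 10 (0.0717 to 0.0833). That of miR-199b-5p was lost in 6, including no scaling (0.0875) and without sham replicate 5 or 6 or LPS replicate 6 or 11 (0.0506 to 0.0658). MiR-221-3p fell by 0.32 ± 0.06 and endothelial miR-126a-3p differed by -0.02 ± 0.06. Liver-specific miR-122-5p was not above background on any array, and neither striated muscle member passed the test (miR-1a-3p 0.13 ± 0.12, miR-133b-3p -0.06 ± 0.12). Of 35 listed members of the Dlk1-Dio3 imprinted cluster on the array, only 2 passed the detection filter, so they do not speak for the cluster. Of these, miR-487b-3p fell by 0.63 ± 0.09 (-0.18 with normexp and -0.32 with the mean of logs over probes) and miR-494-3p as above. Red-cell miR-451a was 5.40-fold higher and miR-144-3p higher by 2.46 log2 units. The miR-144-3p value is not exact because 2 of 4 sham arrays detected it. Its log2 difference was 0.997 with normexp (adjusted p = 0.0272) and 4.11 in the deposited ratio table (adjusted p = 0.0873). The groups overlapped, with an SD of 1.15 and 1.21 log2 units for miR-451a in sham and LPS (adjusted p = 0.0285 and 0.0235 for miR-451a and miR-144-3p). Both calls were lost when any of sham replicate 6, sham replicate 7, LPS replicate 6 or LPS replicate 11 was left out, that of miR-451a also without LPS replicate 12.

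The 12 largest falls were led by miR-6975-5p (by 1.12 ± 0.16), miR-7080-5p (by 1.02 ± 0.20) and miR-190b-5p (to 0.499 of the sham level), and included miR-3070-2-3p, miR-6980-5p, miR-6401, miR-7234-3p, miR-7028-5p, miR-6904-5p, miR-6971-5p, miR-30c-1-3p and miR-8119, which fell by 0.87 to 0.97, miR-7234-3p and miR-8119 being detected on 3 of 4 LPS arrays. With normexp all 12 differences were over 1.5 times smaller, from -0.49 to -0.26, while miR-6971-5p and miR-30c-1-3p were at -1.47 and -1.43 in the deposited ratio table. With slide column as a block, 8 of these 12 were not called (adjusted p = 0.0525 to 0.0721): miR-190b-5p, miR-3070-2-3p, miR-6980-5p, miR-6401, miR-7234-3p, miR-7028-5p, miR-6904-5p and miR-8119. Their deviations from the group means went together across arrays, with a median pairwise correlation of 0.959, against 0.178 among the 12 largest rises. Without the 20 miRNAs that followed this shared profile at a correlation over 0.9, as examined after seeing the data, 116 miRNAs changed, 50 higher and 66 lower.

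**Figure D4:**
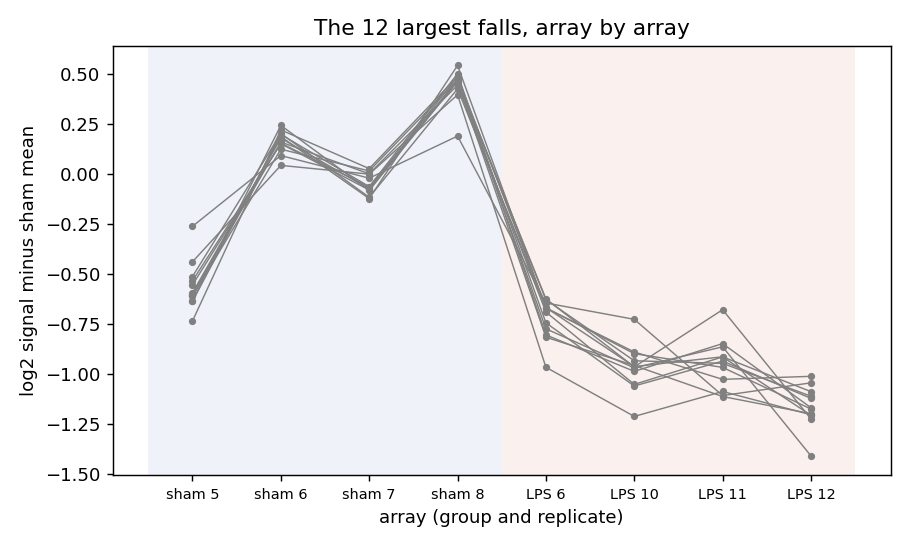
Log2 signal of the 12 largest falls on each array, minus the mean of the sham arrays, with 1 line per miRNA and the sham arrays on the left. The lines run together across the sham arrays and less closely across the LPS arrays.

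Further rises were seen for miR-3077-5p (4.53-fold), miR-6931-5p (3.49-fold), miR-3082-5p (3.06-fold) and miR-6538 (2.74-fold), which with normexp had log2 differences of 0.83, 1.36, 0.63 and 0.89, and for miR-7040-5p, miR-3091-5p, miR-669n and miR-182-5p, which were below background in sham and whose brightest probes were at least 1.70-fold, 1.35-fold, 1.43-fold and 1.28-fold higher. These bounds hold for the background subtraction used: with normexp the log2 differences of these 4 were 0.31, 0.29, 0.15 and 0.06, and they were 7.32, 6.91, 1.11 and 2.06 in the deposited ratio table. The miR-182-5p call was lost in 5 of 29 alternatives, including slide column as a block (adjusted p = 0.0613) and without sham replicate 8 (0.0565), and that of miR-3091-5p with the mean of logs over probes (0.158). Among 22 GC-rich or fragment-like entries 5 rose and 3 fell (camera adjusted p = 0.117), with miR-574-5p (2.08-fold, 0.66 log2 with normexp) and miR-466i-5p (2.00-fold) among the risers and miR-5100, which fell by 0.37 ± 0.07 (-0.23 with cyclic loess and -0.56 with quantile normalization). The probes of miR-574-5p, miR-466i-5p, miR-3082-5p, miR-669n and miR-1187 all carry AC repeats.

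The list tests limit what can be said of groups: 3 of 14 lists were called with the preset correlation, and 0 with an estimated correlation, where fry called 6. Besides those 3, fry called the leukocyte list (adjusted p = 0.00137), the tubule list (0.00706) and the miR-30 family (0.0276). Adjusted over the list alone, the counts of members that rose or fell were the same in all lists except the miR-200 family. The leukocyte and miR-29 lists each had camera adjusted p = 0.0681, the miR-34 family 0.170 and smooth muscle and stroma 0.586. Over 30 alternatives, the leukocyte list gained the call in 8, the miR-29 list in 7 and the GC-rich or fragment-like list in 4. The tubule list and the miR-30 family each gained it in 1. Slide row and group cannot be told apart.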

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

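Tests on the split counts of higher and of lower calls, on the repeat rank, on brightness, on genomic position, on scaling, on a misplaced array and on red and white blood cells were chosen after the results they bear on had been seen. The tests on miRNAs left out of the comparison were set beforehand.

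Of 170 groups of 4 arrays examined, 8 held an array far from the other 3, where chance gives about 8.50. For miR-146a-5p, LPS replicate 10 stood apart at -0.18, as did LPS replicate 10 for miR-199a-5p (-0.55), miR-322-5p (1.02) and miR-322-3p (-4.50), and sham replicate 6 for let-7i-5p (2.83) and miR-182-5p (-4.32). For miR-21a-3p, sham replicate 8 was at -4.56 and for miR-7040-5p sham replicate 5 was at -4.57. For both, and for miR-182-5p and miR-322-3p, the other arrays of the group were at the floor, so any value above it stood apart. The number given by chance does not allow for the floor.

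Of 9 control probes outside the comparison, 4 were higher on every LPS array than on every sham array: the labelling spike-ins dmr_285 (by 0.34 log2) and dmr_31a (by 0.11), and hur_6 (by 0.30) and mr_1 (by 0.11). The control hur_2 was lower on every LPS array, by -0.04. Each of these 5 had exact permutation p = 0.0286, the smallest possible, and 0.0514 after adjustment over the 9, while the other 4 differed by -0.03 to 0.04 and did not separate the groups.

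The real grouping gave 136 changed miRNAs, and 1 of the 35 splits of the 8 arrays, the real one, gave as many, the highest other giving 2. It was likewise 1 of 35 for higher and for lower calls, the smallest share that 35 splits allow. Chance is therefore argued against for these counts but not excluded. The other splits mix LPS and sham arrays, which widens their spread and lowers their counts. The real split also divides the arrays by slide row. For the 3 shifted lists chance stays open: 18 of the 35 splits gave as many, and the highest other gave 8.

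The largest falls varied together between arrays. The 20 miRNAs sharing the profile include 11 of the 12 falls but not miR-30c-1-3p. Of the 20, 15 have probes that match repeats of CCCTAA, mismatches allowed, at a score of 6 or more. Among 318 other tested miRNAs, 6 reach this score. The probes of the 15 may bind RNA with UUAGGG repeats rather than the named miRNAs. Going with this, 21 untested miRNAs with such probes followed the profile with a median within-group correlation of 0.565, against 0.002 for 598 others. Random draws of miRNAs gave permutation p = 1e-04, the smallest the draws can give. That p measures spread over miRNAs with similar probes, not between samples. That this unit ranked 1 of 700 hexamer units in the 20 only restates where the repeat was seen. Low brightness is argued against, as 150 other tested miRNAs within the range of their sham levels, a set redefined after a narrower version had been seen, had a median correlation of -0.193. One genomic cluster is argued against, as the genes of 0% of the 20 lay within 50 kb of another, on 12 chromosomes, in the RefSeq table used after only 5 had a probe mapped on mm9. A real decrease of such an RNA after LPS, or of each miRNA, was not tested.

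The probes with AC repeats rose together, by 0.86 to 1.61 log2. The scaling used is too small to make this rise: its log2 factor differed by 0.08 between groups, and the median difference was 1.09 without it. Given that factor, leaving scaling out could not have ended the rise, so it is no separate test. Binding of an RNA with UG repeats stays open: 24 untested miRNAs with such probes had a median difference of 0.39, between the limits set beforehand. Random draws of miRNAs gave permutation p = 1e-04, the smallest the draws can give, which measures spread over miRNAs with similar probes and not between samples. Induction of these miRNAs by LPS was not tested separately.

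MiR-451a and miR-144-3p rose unevenly. The rise of miR-451a did not rest on 1 array, as its lowest log2 difference over the fits without 1 array was 2.02. That test cannot tell whether 1 array made the rise uneven. Without LPS replicate 10, the lowest LPS array for both, miR-451a and miR-144-3p each differed by 2.99 (adjusted p = 0.0108 and 0.00955). Red blood cells left in the tissue stay open: the within-group correlation of miR-486a-5p with miR-451a was 0.969 (rho 0.976, exact permutation p = 0.00174, adjusted 0.00347 over 4 miRNAs, and 0.964 without the 2 farthest arrays), but miR-486a-5p was well above background on 0 of 4 sham and 2 of 4 LPS arrays, so this does not settle it. Leukocytes of whole blood could not be settled, with a mean correlation of 0.317 for miR-142a-3p and miR-223-3p. An effect of LPS on erythroid RNA in the kidney was not tested and stays open.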

How the results depend on the processing

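The scaling to labelling spike-ins and the removal of probe groups were added after seeing the data. Changed miRNAs numbered 60 without a filter, 23 with a 2-fold minimum and 80 with slide column as a block. Higher miRNAs numbered 29 without a filter and 19 with the 2-fold minimum. Lower miRNAs numbered 53 with the percentile over all probes, 49 without scaling, 31 without a filter, 4 with the 2-fold minimum, 45 with the column block, 53 with the deposited ratio table and 151 with spike-in scaling, which also moved the median difference of all miRNAs from -0.08 to -0.23 and left 34 higher. Shifted lists numbered 7 with the filter on any array, 6 without a filter, 6 with the manufacturer's detection call, 5 with the column block, 5 with spike-in scaling, 5 without AC-repeat probes, 0 with an estimated correlation and 6 with fry. Fewer calls without a filter follow from testing 1881 miRNAs, and fewer with the 2-fold minimum from its added cutoff. The cause of the other changes in these counts was not tested. Leaving out 1 array gave 94 to 148 changed, 34 to 55 higher, 55 to 100 lower and 3 to 5 shifted lists, and differences of -3.25 to 9.75 detected miRNAs and 0.05 to 0.11 in the log2 scaling factor; the differences in detection and scaling stayed short of the threshold. MiR-29a-5p turned to -0.000427 with normexp, and the let-7 family was called in the other direction without a filter (median -0.0127). Over the alternatives fitted per miRNA, named miRNAs stayed on the same side of the threshold in 2254 comparisons. They lost the call in 154, besides miR-29a-5p with normexp, and gained it in 38. In 50 of the 2254 the sign changed, for 16 miRNAs called on neither side. MiR-21a-5p (2.07 to 2.33), miR-155-5p (0.99 to 1.84) and miR-223-3p (0.58 to 0.95) were called in all 30 alternatives fitted per miRNA, which leave out the 2-fold minimum that miR-223-3p, at 1.81-fold, misses. No paired analysis was possible by replicate number, because the groups share only number 6; the column block pairs arrays by slide position alone. Signal over background limits the dim miRNAs, for which bounds are given.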

Other observations

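Arms and neighbours of the same precursor or cluster did not always move alike. MiR-132-3p rose by 1.39 ± 0.12 log2 while miR-212-3p fell by 0.45 ± 0.07, and miR-221-3p fell by 0.32 ± 0.06 while miR-222-3p differed by 0.08 ± 0.06; these differences between miRNAs were not tested. Among probes with GT repeats, the opposite strand of the AC repeats, 7 miRNAs were tested and miR-466f-3p (-0.37 ± 0.11), miR-466h-3p (-0.33 ± 0.08), miR-467f (-0.32 ± 0.10) and miR-669c-3p (-0.30 ± 0.09) fell. These were chosen after their values were seen. The brightest entry, miR-6366, fell by 0.31 ± 0.06.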
